A study of Mus musculus with 16 samples.

How the data were processed

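Total RNA of peritoneal macrophages was hybridised to 16 two-colour Agilent arrays, 8 for mice given heat-killed and 8 for mice given live Mycobacterium leprae, each with RNA of PBS-injected mice in the other channel. Per the labels, RNA was extracted with Trizol and labelled with a low-input Agilent amplification kit, the injected mouse was in Cy5 and the PBS mouse in Cy3 on every array, and the PBS mice carry 16 numbers. The intensity values used were the mean spot and median local background signals, which per the file headers are unnormalised output of Agilent Feature Extraction (version 9.5.3 in the submitters' processing notes), 1 array per file. The deposited log10 ratios of Cy5 over Cy3 and the processed intensities came, per the file headers, from background subtraction with spatial detrending and from linear and lowess dye normalisation within each array. A further table of log2 values deposited by the authors for the same arrays holds 41174 rows, all matched to a spot by its feature number. Its columns had medians of -0.013 to 0.0186 and 0% to 25.9% missing values, over 1% in 5 columns. They correlated with each array's log10 ratios at r = 0.839 to 0.97 with slopes of 2.27 to 3.12, which sets their scale to about log2 and their direction to Cy5 over Cy3. The normalisation behind that table is not given in the sources used here, so it served only as an alternative.

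Each array held 45018 spots, of which 1639 were controls, and the other 43379 represented 41174 distinct probes, 245 of them with 10 spots each. Probes were named through a table of RefSeq genes of assembly GRCm38.p6, used for names only: 22951 by accession, 6659 by symbol and 3109 by an older synonym, while 8455 kept the name in the file, which gave 27670 names. Probe positions are those of build mm7 in the files. Signals were corrected with normexp (offset 50) in limma 3.58.1 (with data.table version 1.17.8 in R 4.3.3), fitted on all spots, and log2 ratios were normalised by loess within each array with weight 0 for control spots. Control spots, spots marked as population outliers in a channel and spots marked as non-uniform in Cy3 were left out, and saturated spots were kept. The scanner software's non-uniformity mark covered 27.3% to 53.2% of spots in Cy5 but at most 0.897% in Cy3. Spots with the Cy5 mark were therefore kept, and leaving them out was an added alternative. Spots of a probe were averaged. The probe with the highest mean intensity stood for its gene, and a gene was tested if at least 1 of its probes was well above background in at least 1 channel on at least 8 arrays. Of the genes tested, 259 (1.85%) were saturated in both channels on all arrays, and 52 had fewer than 4 values in a group. Probes of a gene often disagreed: among 829 called genes with another probe in the heat-killed comparison, 238 (28.7%) had a probe of opposite sign, and 398 of 1241 (32.1%) in the live comparison.

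Groups were taken from the labels. The design, made before the data were examined together with the gene lists, the rule for named genes and most alternatives, assumed 16 separate PBS mice. The values go against that, because the Cy3 channel varied less between arrays than Cy5, but PBS mice that are alike are not excluded. The tests were kept as designed, and if 1 control RNA was shared, the ratio against 0 leaves out the control's own spread. All 16 log2 ratios entered 1 limma fit (lmFit and eBayes with an intensity trend) with a mean per group and no covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Errors given beside a log2 ratio are SDs over the arrays of a group. No 2 arrays had identical Cy5 signals. The 35 gene lists held 668 genes, 557 of them tested, and 34 lists with at least 4 tested genes were compared with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. No list call held with an estimated correlation. Median, mean and test direction differed in sign for 5, 6 and 2 lists in the heat-killed, live and direct comparison, none of them called.

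Named genes were, in each comparison, the 10 largest increases and decreases among named genes with an adjusted p under 0.05 and the sign of the mean on at least 7 of 8 arrays, up to 4 members with the smallest p of each list, and, where fewer than 5 genes passed, the 10 with the smallest p. Some of these are left out here, such as genes whose Cy3 signal varied between arrays or was not well above background on any array. Each slide held 4 arrays of 1 group and each of 2 scan days held 4 arrays of each group, so slide was used as a random block (consensus correlation -0.0013) and scan day as a block and for separate fits. Alternatives also covered the background correction, the processed intensities, the deposited log2 table, median centring, scaling between arrays, filters on dim probes, the mean of all probes, array weights, replicate number as a block, leaving out each array, the Cy5 channel alone and assumed spreads of the PBS control.

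The fits were tested on data simulated independently for each gene with the residual SDs of the fit, with 200 of 14010 genes changed. For heat-killed against PBS they recovered 79.1%, 98.5% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale with 12 false calls, and for live against PBS 89.6%, 97% and 98.5% with 19. Relations between lists and the figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The median spot SD of log2 ratios over replicate spots was 0.211 to 0.276 per array. The number of arrays limits the precision. The mice were grown and harvested separately per the series' design text, and with a shared control the p-values cover the spread between injected animals but not that between PBS animals.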

Results

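Gene expression was measured in peritoneal macrophages of BALB/c nude mice, which carry a defective Foxn1 gene and lack a functional thymus. The cells were taken 2 weeks after an intraperitoneal injection. 8 mice had received 2000000 heat-killed and 8 mice 2000000 live Mycobacterium leprae, the slow-growing bacillus of leprosy, whose main host cells are macrophages and Schwann cells. RNA of each injected mouse, labelled with Cy5, was hybridised together with RNA of PBS-injected control mice, labelled with Cy3, on a whole-genome oligonucleotide array. This gave 16 arrays, 8 in each of 2 groups, and no array had the dyes exchanged. The median spot signal was 385 to 617 in Cy3 and 179 to 427 in Cy5, over a median local background of 84 to 136 and 38.5 to 42.5. Between 35.2% and 47.1% of the probes were well above background in Cy3, and between 43% and 65.2% in Cy5. The number of arrays limited the precision: the median half-width of the 95% confidence interval of a log2 ratio was 0.168 against PBS and 0.238 between the injected groups.

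The PBS channel varied less between arrays than the channel of injected mice, in which single genes differed widely. Oas1a, an interferon-induced oligoadenylate synthetase, had a Cy5 log2 signal of at least 12.3 on 4 arrays, 2 of each group, and of at most 8.86 on the others, whereas its Cy3 signal was 11.4 ± 0.13 (SD, n = 16). Acod1, the enzyme that makes the antimicrobial metabolite itaconate, was at or above 13.5 in Cy5 on 5 arrays and at or below 11.9 on the others, with a Cy3 signal of 9.64 ± 0.22 (SD, n = 16). In all, 6 genes (Acod1, Ephx2, Htra1, Mela, Oas1a and Oas1f) took separate levels in Cy5 and not in Cy3, and 0 genes did so in Cy3 and not in Cy5. These genes were singled out after their values were seen, and this count describes levels without a test. Counted in each channel alone, 44 genes took separate levels in Cy5 and 38 in Cy3, and 76 tested genes had a Cy3 SD over 1. The SD within a slide was smaller in Cy3 for 34 of 34 lists, with a median ratio to Cy5 of 0.23. It was 0.0297 against 0.786 for interferon-gamma-inducible genes and 0.0104 against 0.012 for ribosomal proteins (ratio 0.867). Of the 28 ribosomal protein genes, 22 were saturated in both channels on all arrays, so their ratio says little about the spread of the RNA. The labels number 16 PBS mice, 1 per array, and 16 alike samples cannot be told from the same RNA on every array. Because 1 shared control is not excluded, the tests against PBS are read as leaving out the control's own spread.

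**Figure D1:**
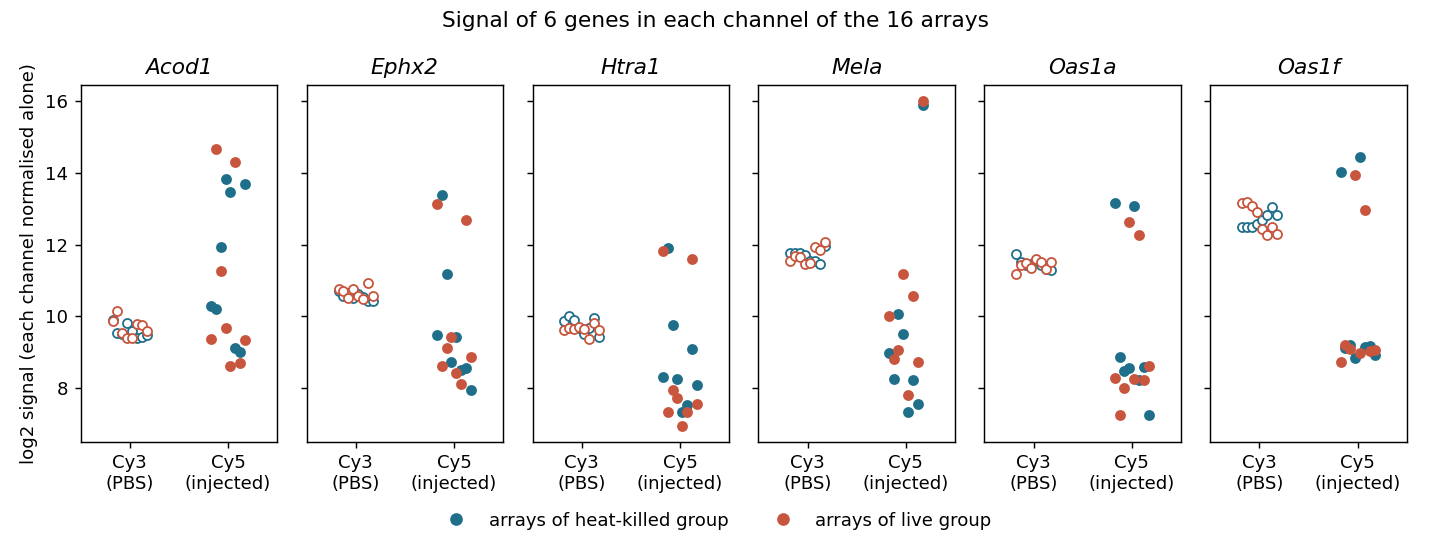
Log2 signal of 6 genes in the Cy3 channel (PBS, open circles) and the Cy5 channel (injected mice, filled circles) of the 16 arrays, each channel normalised alone, with arrays of the heat-killed group in blue and of the live group in red. The Cy3 values of each gene lie close together (Oas1a 11.4 ± 0.13, SD, n = 16), while the Cy5 values form separate levels that hold mice of both groups.

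The question of the comparison of heat-killed bacilli with PBS was which genes dead bacilli left changed 2 weeks later. Cell cycle and NK cell genes were higher, and mast cell and type I interferon-stimulated genes lower, in mice given heat-killed bacilli than in the PBS control. Of 24 cell cycle genes, 18 rose and the other 6 did not pass (23 rose adjusted over the list alone), with a mean log2 ratio of 0.54 ± 0.54 (SD, n = 8) and a positive mean on 6 of 8 arrays. Pcna, the sliding clamp of DNA replication, rose by 0.35 ± 0.16 (adjusted p = 0.000954), Mcm3, a subunit of the replicative helicase, by 0.29 ± 0.09 (0.00666), and Cdc20, an activator of the anaphase-promoting complex, by 0.62 ± 0.57 (0.0122). The list's camera adjusted p was 2.79e-09, its median was 0.59 and 0.47 on the first and second scan day (6.41e-09 with scan day as a block), and the call was lost at adjusted p = 0.474 with an estimated correlation. Of 15 NK cell markers, 11 rose and the other 4 did not pass (14 rose adjusted over the list alone), with a mean of 0.86 ± 0.62 (SD, n = 8), positive on 8 of 8 arrays. Gzma, a granule protease of cytotoxic lymphocytes, rose by 1.59 ± 1.09 (adjusted p = 0.0156), Nkg7, a cytotoxic granule membrane protein, by 1.16 ± 0.68 (0.0122), and Ifng, the cytokine interferon-gamma, by 1.07 ± 0.74 (0.012; Cy3 well above background on only 6 of 16 arrays). The NK list had an adjusted p of 9.5e-06 and medians of 0.53 and 1.13 on the scan days (1.18e-05 blocked), and adjusted p = 0.599 with an estimated correlation.

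Mast cell markers fell on 8 of 8 arrays, with a mean of -0.92 ± 0.27 (SD, n = 8). Of the 12 measured, 10 fell and the other 2 did not pass (11 fell adjusted over the list alone). The serotonin transporter Slc6a4 fell by 1.29 ± 0.25 (adjusted p = 0.000407), the mast cell receptor Mrgprb2 by 1.14 ± 0.30 (0.000445), and Fcer1a, a chain of the high-affinity IgE receptor, by 0.92 ± 0.38 (0.000512). The list's adjusted p was 6.66e-09, with medians of -0.75 and -1.10 on the scan days (1.62e-08 blocked), and adjusted p = 0.428 with an estimated correlation. Of 8 eosinophil markers, 2 fell and the other 6 did not pass (3 fell adjusted over the list alone). They were Ccr3, the eotaxin receptor, at -0.83 ± 0.67 (adjusted p = 0.0121), and Il4, a cytokine that mast cells also make, at -0.67 ± 0.23 (0.000325; Cy5 well above background on only 4 of 8 arrays). The eosinophil list had a mean of -0.50 ± 0.41 (SD, n = 8), an adjusted p of 0.00231, medians of -0.50 and -0.51 on the scan days (0.00317 blocked), and adjusted p = 0.428 with an estimated correlation.

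Type I interferon-stimulated genes fell as a list after heat-killed bacilli, while the list of interferon-gamma-inducible genes rose, with 3 of its 18 genes passing. Of 23 type I genes, 9 fell and the other 14 did not pass (10 fell and 1 rose adjusted over the list alone), with a mean of -0.36 ± 0.40 (SD, n = 8), negative on 7 of 8 arrays. Irf7, the transcription factor that amplifies interferon production, fell by 1.04 ± 0.64 (adjusted p = 0.00245), the antiviral GTPase Mx2 by 0.83 ± 0.43 (0.000238), and Usp18, a brake on interferon receptor signalling, by 0.79 ± 0.48 (0.00281). The list's adjusted p was 0.000185, its medians were -0.32 and -0.40 on the scan days (0.00031 blocked), and the call was lost with fry (0.0628) and at adjusted p = 0.664 with an estimated correlation. Of 18 interferon-gamma-inducible GTPases and effectors, 3 rose, also when adjusted over the list alone, and the other 15 did not pass. They were Acod1 at 2.07 ± 1.90 (adjusted p = 0.028, but 0.0611 with replicate number as a block), the GTPase Gbp3 at 0.50 ± 0.49 (0.0403) and the transcription factor Irf8 at 0.27 ± 0.24 (0.0184). The list mean was 0.49 ± 0.68 (SD, n = 8) and positive on 5 of 8 arrays, with an adjusted p of 0.013, medians of 0.42 and 0.35 on the scan days (0.0158 blocked), no call with fry (0.159), and adjusted p = 0.664 with an estimated correlation.

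Genes of cholesterol synthesis, lysosome, alternative activation, T cells, mesothelium and fibroblasts made up 6 further called lists. Cholesterol biosynthesis and uptake fell to a mean of -0.14 ± 0.13 (SD, n = 8), with 6 of 22 genes lower and the other 16 not passing (8 lower adjusted over the list alone). Srebf2, the master regulator of the pathway, was at -0.32 ± 0.25 (adjusted p = 0.00306). This list had an adjusted p of 0.00666, medians of -0.11 and -0.16 on the scan days (0.00775 blocked), and adjusted p = 0.474 with an estimated correlation. Of 22 lysosome and phagosome genes, 8 fell and 1 rose, also when adjusted over the list alone, among them the lysosomal calcium channel Mcoln1 at -0.40 ± 0.11 (adjusted p = 1.68e-05) and the macrophage marker Cd68 at -0.64 ± 0.30 (0.000651). That list's median of -0.05 (adjusted p = 0.0195, 0.0236 blocked, and adjusted p = 0.599 with an estimated correlation) had no steady direction: it was 0.02 on the first and -0.13 on the second scan day, and 0.03 relative to all genes when arrays were centred on their median. Of 17 genes of alternative activation, 5 fell and 2 rose (9 and 2 adjusted over the list alone), with a mean of -0.29 ± 0.28 (SD, n = 8). Vsig4, a complement receptor of resident macrophages, fell by 0.80 ± 0.47 (adjusted p = 0.0026) and the lectin Mgl2 by 1.10 ± 0.67 (0.0119), while Arg1, arginase, rose by 0.67 ± 0.34 (0.000995). T cell markers had a mean of 0.33 ± 0.39 (SD, n = 8), with 3 of 13 higher, also over the list alone, such as Lck, a kinase of T cell receptor signalling, at 0.67 ± 0.43 (adjusted p = 0.00405). The mice lack a functional thymus, and which cells carried these transcripts was not tested. The alternative activation and T cell lists both had an adjusted p of 0.0398 and of 0.0523 with scan day as a block. Their medians were -0.33 and -0.27, and 0.55 and 0.16, on the scan days, and the calls were lost at adjusted p = 0.474 and adjusted p = 0.664 with an estimated correlation. The rotation test fry called the former (0.028) but not the latter (0.0926). Mesothelial and fibroblast markers fell with 2 of 5 genes each, also over the list alone, such as the keratin Krt18 at -0.50 ± 0.42 (adjusted p = 0.0104) and Pi16, a marker of adventitial fibroblasts, at -0.54 ± 0.25 (0.00193). Their list means were -0.36 ± 0.33 and -0.29 ± 0.37 (SD, n = 8), their medians -0.24 and -0.44, and -0.15 and -0.47, on the scan days. Their adjusted p was 0.016 and 0.0494, 0.0158 and 0.0525 blocked, with adjusted p = 0.428 and adjusted p = 0.474 with an estimated correlation. The fibroblast call was also lost without the live 7 array (0.0613), which enters through the shared estimate of the spread.

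Clec4g, Fscn1 and Cyp26a1 had the largest decreases among the genes named by the fixed rule. Clec4g, a C-type lectin, fell by 2.66 ± 0.44 on the log2 scale, 6.32-fold (SD, n = 7, adjusted p = 3.84e-06), Fscn1, an actin-bundling protein of mature dendritic cells, by 2.05 ± 0.27 (8.6e-07), and Cd209a, a lectin of the DC-SIGN family, by 1.72 ± 0.50 (0.000127). Of 12 dendritic cell markers, 4 fell and 1 rose. Their list was not called by camera after heat-killed bacilli (adjusted p = 0.443) but was by fry (0.0145). After live bacilli neither called it (0.962 and 0.499). Cyp26a1, which degrades retinoic acid, fell by 1.96 ± 0.87 (0.00209), while its relative Cyp26b1 rose by 1.44 ± 0.90 (0.00372). Col18a1, a basement membrane collagen, fell by 1.74 ± 0.81 (0.000175; -1.21 at its other probe), the chemokine Cxcl13 by 1.45 ± 1.10 (0.00372) and Pdk4, an inhibitor of pyruvate dehydrogenase, by 1.45 ± 0.81 (0.000212). Myh7, a muscle myosin, fell by 1.65 ± 1.00 (0.000954) and Rprm, a mediator of cell cycle arrest, by 1.51 ± 0.52 (9.44e-05). Tgm2, a protein cross-linking transglutaminase, rose by 1.39 ± 0.89 (0.00758) and Klra7, a Ly49 receptor of NK cells, by 1.31 ± 0.80 (0.00872). In build mm7, on which the array's annotation rests, the probes lie on chromosome 14 at 97488885 to 97488945 (Acod1), chromosome 8 at 3678594 to 3678653 (Clec4g), chromosome 5 at 142005563 to 142005622 (Fscn1), and chromosomes 19 at 37401759 to 37401818 (Cyp26a1) and 6 at 84601274 to 84601333 (Cyp26b1). The exons they match are not given in the sources used here.

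Over 14010 genes, limma with Benjamini-Hochberg adjustment called 2388 changed after heat-killed bacilli, 1193 higher and 1195 lower, 80 of them by at least 2-fold. With scan day as a block the count was 2433, and within the first and second scan day, with 4 arrays each, it was 323 and 452. Leaving out all spots marked as non-uniform in Cy5 gave 408. Centring each array on its median in place of loess moved the median of all genes by 0.13 and the split to 3826 higher and 397 lower. With Cy3 as a pool of 16 mice that vary like the injected ones limma called 864 genes, and with Cy3 as 1 such mouse 0 genes (133 at unadjusted p under 0.05). Of the genes given above as changed, Acod1, Gbp3 and Irf8 did not pass under the pool (adjusted p = 0.108, 0.138 and 0.0825), nor did the NK cell genes Gzma, Nkg7 and Ifng (0.0741, 0.0628 and 0.0623), nor Cdc20, Mgl2, Ccr3 and Krt18 (0.063, 0.0617, 0.0624 and 0.0562).

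The comparison of live bacilli with PBS asked the same of mice that had received viable bacilli. Mast cell and cholesterol genes were again lower and cell cycle and NK cell genes again higher than in the PBS control. Large peritoneal macrophage and lipid genes were also called lower as lists. All 12 mast cell markers measured fell, also when adjusted over the list alone, with a mean of -1.06 ± 0.69 (SD, n = 8), negative on 8 of 8 arrays. Slc6a4 fell by 1.55 ± 0.86 (adjusted p = 4.31e-05), the tryptase Tpsb2 by 1.45 ± 1.02 (0.000234), the transcription factor Gata2 by 1.25 ± 0.76 (0.000282) and Kit, the stem cell factor receptor on which mast cells depend, by 0.94 ± 0.64 (0.000349). The list's adjusted p was 1.05e-08, with medians of -1.01 and -1.05 on the scan days (2.61e-08 blocked), and adjusted p = 0.58 with an estimated correlation. Of 24 cell cycle genes, 17 rose and the other 7 did not pass (20 rose adjusted over the list alone), with a mean of 0.55 ± 0.35 (SD, n = 8), positive on 7 of 8 arrays. Mki67, a marker of cycling cells, rose by 0.97 ± 0.66 (adjusted p = 0.00771), the spindle protein Tpx2 by 0.70 ± 0.39 (0.00711) and Pcna by 0.42 ± 0.18 (0.000118). The list had an adjusted p of 1.04e-07, medians of 0.41 and 0.67 on the scan days (2.05e-07 blocked), and adjusted p = 0.773 with an estimated correlation. Of 15 NK cell markers, 5 rose and the other 10 did not pass (12 rose adjusted over the list alone), Gzma at 1.27 ± 1.65 (adjusted p = 0.0354) and the NK receptor Ncr1 at 0.80 ± 0.99 (0.0342) among them. The NK list mean was 0.69 ± 0.96 (SD, n = 8) and positive on 5 of 8 arrays, with an adjusted p of 0.000736, medians of 0.50 and 0.87 on the scan days (0.000798 blocked), no call with fry (0.0957), and adjusted p = 0.773 with an estimated correlation.

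Large peritoneal macrophage markers fell after live bacilli, with 8 of 19 lower and the other 11 not passing (10 lower adjusted over the list alone) and a mean of -0.28 ± 0.16 (SD, n = 8), negative on 8 of 8 arrays. Ltbp1, which binds latent TGF-beta, fell by 0.59 ± 0.40 (adjusted p = 0.000283), Tgfb2, one of the TGF-beta cytokines, by 0.47 ± 0.33 (0.00168), the adhesion receptor Selp by 0.36 ± 0.26 (0.00304) and Cxcl13 by 1.30 ± 0.89 (0.00468). The list's median of -0.21 was -0.25 and -0.17 on the scan days, and 0.01 with arrays centred on their median, or -0.14 relative to all genes. Its adjusted p was 0.000396 (0.000512 blocked), and adjusted p = 0.609 with an estimated correlation. Of 18 genes of lipid droplets and lipid uptake, 7 fell and 1 rose (8 and 1 adjusted over the list alone), with a mean of -0.23 ± 0.10 (SD, n = 8). Fabp4, a fatty acid carrier, fell by 1.79 ± 0.60 (adjusted p = 6.38e-05; -1.34 at its other probe), Soat1, which esterifies cholesterol for storage, by 0.64 ± 0.33 (0.000299) and Fabp3 by 0.65 ± 0.33 (0.00351). The list's adjusted p was 0.0122 and its medians -0.13 and -0.25 on the scan days (0.0135 blocked), with adjusted p = 0.337 with an estimated correlation. After heat-killed bacilli the lipid list had a mean of -0.14 ± 0.13 (SD, n = 8), with 6 of 18 genes lower. There it was not called by camera (adjusted p = 0.0536) but was by fry (0.0112). Between live and heat-killed mice camera called neither the lipid list (adjusted p = 0.277) nor that of cholesterol biosynthesis and uptake (0.218). Of 22 genes of cholesterol biosynthesis and uptake, 9 fell and 1 rose (10 and 1 adjusted over the list alone), among them Fdft1, squalene synthase, at -0.57 ± 0.28 (adjusted p = 0.000532) and Msmo1 at -0.49 ± 0.24 (0.000237). The list mean was -0.22 ± 0.13 (SD, n = 8), the adjusted p 0.000396, the medians -0.34 and -0.12 on the scan days (0.000558 blocked), and adjusted p = 0.58 with an estimated correlation. Of 22 lysosome and phagosome genes, 7 fell and 1 rose (8 and 2 adjusted over the list alone), with a median of -0.11 that was -0.01 and -0.12 on the scan days and 0.09 with arrays centred on their median, or -0.06 relative to all genes. Atp6v1a, a subunit of the lysosomal proton pump, rose by 0.48 ± 0.23 (adjusted p = 0.00228). This list's adjusted p was 0.0163 (0.0139 blocked), and adjusted p = 0.773 with an estimated correlation.

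Abca1, the transporter that exports cellular cholesterol, rose by 1.01 ± 0.28 after live bacilli (SD, n = 8, adjusted p = 2.19e-05), while 4 of the 12 genes of its list, cholesterol efflux, fell and the list was not called (mean -0.06 ± 0.08, adjusted p = 0.448). The chaperone genes Dnaja1, Dnajb1 and Hspa1a rose by 1.03 ± 0.23 (1.97e-05; 0.69 and 0.75 at other Dnaja1 probes), 0.69 ± 0.28 (0.0001) and 0.87 ± 0.60 (0.00236), although their list of immediate early and heat shock genes was not called (mean 0.11 ± 0.06, adjusted p = 0.442). Pbk, a mitotic kinase, rose by 1.11 ± 0.52 (0.000721; Cy3 well above background on only 6 of 16 arrays), and the neutrophil chemokine Cxcl2 by 0.86 ± 0.60 (0.00111). Clec4g fell by 2.20 ± 0.93 (1.29e-05), Cyp26a1 by 2.05 ± 1.52 (0.000857), Col18a1 by 1.70 ± 0.76 (0.000108; -1.01 at its other probe), Fscn1 by 1.47 ± 0.71 (1.97e-05) and the chemokine Cxcl12 by 0.93 ± 0.24 (9.64e-06). Acod1 stood at 1.30 ± 2.19 and did not pass (adjusted p = 0.135), and its difference from the heat-killed group was -0.77 (adjusted p = 0.893). Neither type I interferon-stimulated genes (mean -0.20 ± 0.39, adjusted p = 0.24), interferon-gamma-inducible genes (0.24 ± 0.84, 0.566) nor class II antigen presentation (0.04 ± 0.09, 0.739) were called as lists.

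Over 14009 genes, limma called 3441 changed after live bacilli, 1734 higher and 1707 lower, 54 of them by at least 2-fold. The array of live 7 stood apart: its means were -0.07 for NK cell, -0.04 for mast cell and -0.09 for cell cycle genes, against 0.80, -1.21 and 0.64 over the other 7 live arrays. Its cholesterol genes were at -0.23 as on the others (-0.22), and lipid and large peritoneal macrophage genes at -0.12 and -0.13 (-0.25 and -0.30). Without it limma called 3715 genes and 7 lists. With scan day as a block the count was 3496, within the first and second scan day 1059 and 1330, and 623 without spots marked as non-uniform in Cy5. Median centring moved the median of all genes by 0.15 and the split to 4637 higher and 490 lower. With Cy3 as a pool of 16 varying mice limma called 1712 genes, Cyp26b1 (1.03 ± 1.06, adjusted p = 0.0725 under the pool) and Birc5 (1.01 ± 0.70, 0.0679), Gzma (0.116) and Ncr1 (0.113) no longer among them, and with Cy3 as 1 varying mouse 0 genes (258 at unadjusted p under 0.05). A gene-specific dye effect remains in both comparisons with PBS.

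**Figure D2:**
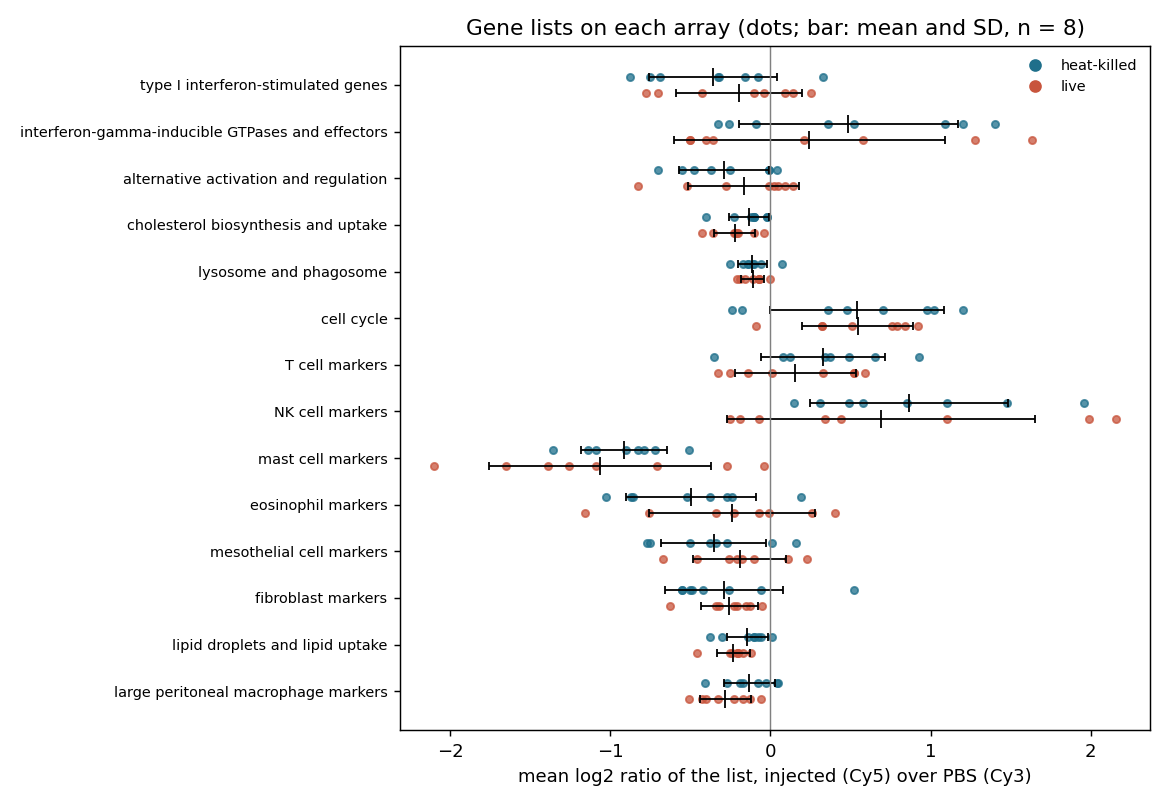
Mean log2 ratio of injected (Cy5) over PBS (Cy3) RNA for each gene list called in any comparison, 1 dot per array, heat-killed in blue and live in red, with bars for the mean and SD of 8 arrays. Mast cell markers lie below 0 on all 16 arrays (heat-killed -0.92 ± 0.27, live -1.06 ± 0.69), and NK cell markers spread more in the live group (0.69 ± 0.96). With arrays centred on their median, which moves all genes, the lysosome median relative to all genes was 0.03 in heat-killed and -0.06 in live mice, and that of large peritoneal macrophage markers -0.14 in live mice.

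The ratios of both groups to PBS were similar gene by gene. Across 14009 genes, which are not independent replicates, the mean log2 ratios had r = 0.777 and a covariance of 0.0425. In both groups 756 genes were called higher, where 148 would be expected from independent lists, and 805 lower, where 146 would be expected; 1 gene was called in opposite directions. Among the genes lower in both were Clec4g, Cyp26a1, Col18a1, Fscn1, Slc6a4 and Cxcl12. The same dye orientation enters both ratios, and so does the same control RNA if 1 was shared, which is not decided. Either can raise these values without any effect of the bacilli. Simulated groups without effect gave r = 0.334, a covariance of 0.00551 and 0 shared calls by limma with a control pooled from 16 mice, and r = 0.889, 0.0874 and 4232 shared calls with a control from 1 mouse, more than were observed. The observed covariance was 0.037 above the former and lay at -0.0449 relative to the latter. The correlation of random sets of 4 arrays of one group with the other group was 0.559 to 0.798 over 100 draws.

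**Figure D3:**
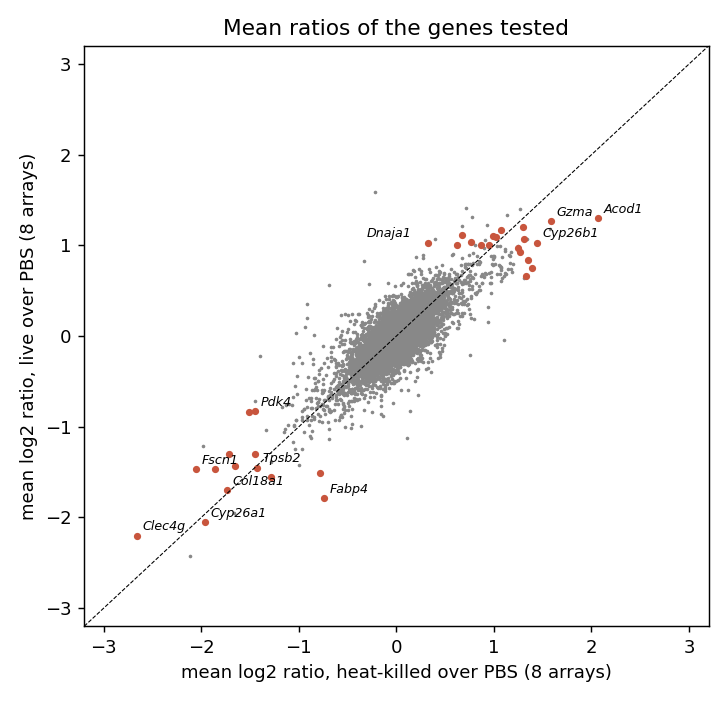
Mean log2 ratio over PBS of each gene tested, heat-killed (8 arrays) on the horizontal and live (8 arrays) on the vertical axis, with named genes in red and equality as a dashed line. The genes lie along the line (r = 0.777 across genes), with Clec4g at -2.66 and -2.20 and Acod1 at 2.07 and 1.30.

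The direct comparison of live with heat-killed bacilli, for which the series is named, called no single gene. Any dye effect common to the arrays cancels in it, and so does the PBS control if 1 RNA was shared. With separate PBS mice their own spread stays in the difference. Each slide held arrays of 1 group only, so an effect of slides cannot be told from a difference between the groups. Txnrd3, a thioredoxin reductase, had a mean log2 ratio of -0.25 ± 0.15 in live and 0.23 ± 0.15 in heat-killed mice, a difference of -0.48 (SD, n = 8, adjusted p = 0.16). Epor, the erythropoietin receptor, was at -0.72 ± 0.24 and -1.45 ± 0.30, a difference of 0.73 (0.16; Cy5 well above background on only 5 of 8 heat-killed arrays), Wdr78 differed by -0.58 (0.265) and Niban1 by 0.73 (0.265), each with 8 of 8 live values on one side of the heat-killed median. The probes of Txnrd3 and Epor lie on chromosome 6 at 89750270 to 89750329 and chromosome 9 at 21837376 to 21837435. The chaperone genes Dnaja1, Dnajb1 and Hspa1a differed by 0.72, 0.54 and 0.67 (adjusted p = 0.366, 0.372 and 0.615), Fabp4 by -1.06 (0.506) and Abca1 by 0.39 (0.667). Over 14009 genes, limma called 0, with 1003 at unadjusted p under 0.05 and a smallest adjusted p of 0.16. With scan day as a block the count was 0 (1047 unadjusted), within the first and second scan day 0 and 0 (1294 and 642), and in the Cy5 channel alone 3. Of these Epor differed by 0.97 (adjusted p = 0.0465), and the other 2, transcripts without a gene name, stood at 0.05 and -0.05 in the ratio (0.963 and 0.96). On data simulated independently for each gene with the residual SDs of the fit, limma recovered 68.7% of genes changed by 0.5 in this comparison. It recovered 94% of those changed by 1 and 100% by 2 on the log2 scale, with 12 false calls. Genes that vary together between mice are absent from that simulation, so these rates do not show that differences of such sizes are lacking.

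Among the 34 lists tested, camera called large peritoneal macrophage markers lower and type I interferon-stimulated genes higher in live than in heat-killed mice. The macrophage markers had a median difference of -0.12, -0.16 and -0.04 on the scan days, with an adjusted p of 0.00385 (0.00317 blocked), and adjusted p = 0.889 with an estimated correlation. Their means were -0.28 ± 0.16 in live and -0.13 ± 0.16 in heat-killed mice (SD, n = 8), and Rarb, a retinoic acid receptor, differed by -0.63 (-0.16 ± 0.39 against 0.47 ± 0.31, adjusted p = 0.372) and Serpinb2, a protease inhibitor, by -0.26 (0.595). Type I interferon-stimulated genes had a median difference of 0.23, 0.02 and 0.40 on the scan days, with an adjusted p of 0.026 (0.0331 blocked), and adjusted p = 0.889 with an estimated correlation. Oasl1, an antiviral oligoadenylate synthetase-like protein, differed by 0.52 (-0.04 ± 0.31 against -0.56 ± 0.30, adjusted p = 0.394), Ifit1 by 0.38 (0.698) and Usp18 by 0.41 (0.753). Adjusted over the list alone, 1 of 19 macrophage markers was lower and 1 of 23 interferon-stimulated genes higher, and the rotation test fry called 0 of the 34 lists. Other splits of the 16 arrays into groups of 8 gave up to 15 lists.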

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

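Of the tests below, those of the PBS channel, of swapped labels and of a mouse without the response were chosen only after the result was seen, and the list settings with scan day as a block and without saturated or separate-level genes were added after the data were seen.

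The PBS channel varied less between arrays than the channel of injected mice. The median SD within a slide was 0.138 in Cy3 and 0.226 in Cy5, and it was larger in Cy5 for 87.8% of 12948 genes. Spots marked as non-uniform in Cy5, 27.3% to 53.2% per array, were kept here, and the SDs without them were not computed. Compression of the Cy3 signal is argued against by the spread of levels across genes, which in Cy3 was 0.948 of that in Cy5. The same PBS RNA on every array stays open: 0 genes took separate levels in Cy3 with a small SD in Cy5, against 6 the other way round, but this rule was settled after a first version had found 0 and 2, too few to decide. PBS mice that are alike, with mice that vary only after bacilli are given, stay open as well. A share of 0.677 of the Cy3 values of these genes lay between the Cy5 levels. By gene these were 16 of 16 values for Ephx2, Mela and Oas1a, 12 for Oas1f, 5 for Htra1 and 0 for Acod1. A pool of mice like the injected ones would give values between the levels, but PBS mice could hold such a level too. If 1 RNA was shared, the 16 values of a gene are repeats.

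Live replicate 7 had a slope of 0.195 on the mean ratios of the other arrays, which themselves had 0.635 to 1.18. A swap of labels with the heat-killed group would put a heat-killed mouse on this array, and the lowest slope among heat-killed arrays was 0.635, far above its own. A noisier hybridisation is argued against by its SD over replicate spots of 0.218, within the 0.211 to 0.276 of all arrays. A mouse without the response, by a label or a sample of PBS origin or by its biology, may explain part of it: over the lists called in live mice the median share of its value in the mean of the other live arrays was 0.0298. The share was 1.02 for cholesterol, 0.486 for lipid droplet and 0.431 for large peritoneal macrophage genes. A dye effect or a deviation of a shared control would enter the ratios of a mouse without response too. These shares therefore do not decide whether a response was lacking completely, and label and biology cannot be told apart.

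Large peritoneal macrophage markers differed by -0.12 and type I interferon-stimulated genes by 0.23 (medians) between live and heat-killed mice, which marked them as differences between groups by camera. Saturated probes are argued against as the whole cause, since the macrophage list kept an adjusted p of 0.0051 without its 4 saturated genes and the interferon list holds 0. Scan day and separate-level genes stay open: days were balanced, so the block (larger adjusted p of both lists 0.0331) could not move the difference, which for interferon genes was 0.02 and 0.40 on the scan days and for macrophage markers -0.16 and -0.04, and Oas1a, the only such interferon gene, went the other way (-0.28), so leaving it out (0.0169) was no test. Chance could not be excluded for these lists: 91 of 100 splits of the arrays gave as many (2 in the real split, up to 15 in another), and the split by scan day gave 6 lists and 3 genes, more than the real one. The median over splits was 5 lists, which may reflect genes that vary together between mice, and a biological difference between live and dead bacilli stays untested.

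For single genes in the direct comparison the splits decide nothing: limma gave 0 genes in the real one (1003 unadjusted), so all 100 had to give as many (highest other 3). For heat-killed against PBS, 1 of 100 patterns of signs given to the arrays, the real one, reached 2388 genes (highest other 2), and for live against PBS 1 reached 3441 (highest other 655), so chance was excluded for both. It was not excluded for the lists against PBS, where 10 patterns reached the 12 of heat-killed (highest other 13) and 28 the 7 of live (highest other 12). Such patterns test the spread between injected mice and exclude neither a dye effect nor a deviation of the control itself.

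A single array lay far from the others of its group in 4 of 107 groups of values tested, where chance gives about 1 in 20, and 0 of them were live 7. Fibroblast markers were at 0.52 in heat-killed 8 and at -0.55 to -0.06 on the other heat-killed arrays, a gap of 0.54 of the range. Lipid droplet genes were at -0.46 in live 1 and at -0.25 to -0.12 on the other live arrays (0.631). The transcript A030005L19Rik was at -0.35 in live 1 and at 0.06 to 0.28 on the others (0.657). The slope on the other arrays was 0.64 in heat-killed 7 and 0.82 to 0.98 in the other heat-killed mice (0.547).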

How the results depend on the processing

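The settings within each scan day, of the PBS control's spread, on non-uniform spots, without unsteady genes and of linear ratios, and for lists the scan day block and those without saturated genes or live 7, were chosen after seeing the data. So was the agreement without live 7 (0.8). No call of the named genes that were followed through the settings reversed; directions of other genes were not compared. The lysosome list turned with median centring, after heat-killed bacilli from -0.05 to 0.15 (0.03 relative to all genes) and after live from -0.11 to 0.09 (relative -0.06), as did large peritoneal macrophage markers after live (-0.21 to 0.01, relative -0.14). Of the 10 largest changes each way and the genes of smallest p, 137, 138 and 50 values (heat-killed, live, direct comparison) kept direction and, where tested, call. Acod1 after heat-killed bacilli lost its call with the replicate number as a block (adjusted p = 0.0611) and under a pool (0.108), and Gzma (0.0741) and, after live bacilli, Cyp26b1 (0.0725) and Birc5 (0.0679) lost theirs under a pool. So did list members given in the report: Nkg7 (0.0628), Ifng (0.0623), Gbp3 (0.138), Irf8 (0.0825), Cdc20 (0.063), Mgl2 (0.0617), Ccr3 (0.0624) and Krt18 (0.0562) after heat-killed and Gzma (0.116) and Ncr1 (0.113) after live bacilli. Genes changed against PBS (2388 and 3441) numbered 4223 after heat-killed bacilli with median centring, 408 and 623 with all non-uniform spots left out, which tests fewer values, 864 and 1712 with PBS as a pool of 16 varying mice, 0 and 0 with PBS as 1 varying mouse (133 and 258 unadjusted), which adds that spread by construction, 323 and 1059 on scan day 1 only and 452 and 1330 on scan day 2 only, with fewer arrays. Leaving out each array gave 1772 to 2667 and 2592 to 3715. Live against heat-killed gave 0 in all ratio settings by limma (474 to 1766 unadjusted) and 3 with the Cy5 channel alone. The agreement of both groups (0.777) was 0.578 with no filter on dim probes, which tests 27669 genes. Lists called (12, 7 and 2) numbered 0, 0 and 0 with an estimated correlation, and fry shared 9, 6 and 0 of them. Of the 12 and 7 lists against PBS, processed signals kept 9 and 6. Median centring kept 9 and 5 of them, while calling 15 and 10. The 2 lists of live against heat-killed became 0 with fry, 5 with processed signals, 5 with median centring, 3 with the replicate block and 3 with the scan day block; the cause was not tested. The replicate numbers gave no sign of pairing: the log2 ratios of same-numbered arrays correlated at 0.0273 to 0.43, within the -0.0684 to 0.63 of all pairs. Of the arrays, 0 correlated best with their own number. That block gave 2192, 3302 and 0 genes and 10 and 7 lists against PBS. Signal over background limits which genes can be tested: 35.2% to 65.2% of probes per channel were well above it.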

Other observations

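The relations below were chosen after the data were seen, and no explanation of them was tested.

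Mice with high NK cell markers had high interferon-gamma-inducible genes and low genes of alternative activation. The signs were the same in both groups, without a test within a group. Across the 16 mice the list means of NK cell markers and interferon-gamma-inducible GTPases and effectors had r = 0.881 (two-sided permutation p = 2e-05, adjusted 0.00014) and rho = 0.897 (1e-05, the smallest that 100000 resamples can give, adjusted 0.00014). Without the 2 mice farthest from the median r was 0.819, within the groups 0.717 for heat-killed and 0.973 for live, and within the scan days 0.877 and 0.92. NK cell markers and alternative activation genes had r = -0.813 (permutation p = 0.00021, adjusted 0.00098) and rho = -0.828 (0.00016, adjusted 0.000747), with -0.721 without the 2 farthest, -0.52 and -0.97 within heat-killed and live, and -0.796 and -0.816 within the scan days. Interferon-gamma-inducible and alternative activation genes had r = -0.9 (2e-05, adjusted 0.00014) and rho = -0.924 (2e-05, adjusted 0.00014), with -0.868 without the 2 farthest, -0.782 and -0.972 within the groups, and -0.956 and -0.881 within the scan days. Markers of some other cells moved along. Those of large peritoneal macrophages (r = 0.327), small peritoneal macrophages and monocytes (-0.196), B cells (-0.167) and mast cells (0.156) did not pass. Nor did those of neutrophils (0.0768), dendritic cells (-0.178) and fibroblasts (0.0262). With NK cell markers, eosinophil markers had r = -0.748 (permutation p = 0.00116, adjusted 0.00406) and rho = -0.771 (0.00073, adjusted 0.00255), with -0.649 without the 2 farthest, -0.498 and -0.885 within the groups and -0.751 and -0.767 within the scan days. Mesothelial markers had r = -0.705 (0.00259, adjusted 0.00725) and rho = -0.678 (0.0051, adjusted 0.0143), with -0.659, then -0.726 and -0.737, and -0.746 and -0.673. T cell markers had r = 0.588 (0.017, adjusted 0.0397) and rho = 0.628 (0.0106, adjusted 0.0228), with 0.53, then 0.169 and 0.881, and 0.613 and 0.724. Erythroid markers passed by rho alone (-0.624, 0.0114, adjusted 0.0228; r = -0.475, 0.0626, adjusted 0.125), with -0.583, then -0.342 and -0.609, and -0.594 and -0.404. These are 14 relations computed, the first 3 and NK cell markers with each of the other 11 lists of cell markers, and the lists compared share no gene. The PBS channel of the same lists varied little, so the relations are between injected mice. Acod1, a member of the interferon-gamma-inducible list, went from -0.13 to 4.30 among heat-killed and from -0.58 to 4.70 among live mice. Its log2 ratio was 4.30 in heat-killed 4, 4.02 in heat-killed 5, 4.07 in heat-killed 8, 4.70 in live 2 and 4.53 in live 6. The NK cell mean was 1.96, 0.49, 1.48, 2.16 and 1.99 on these arrays, in the same order.

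Ephx2, an epoxide hydrolase, and Htra1, a secreted serine protease, were high together in heat-killed 2, live 1 and live 7. Their Cy5 log2 signals there were 13.38 and 11.9, 13.14 and 11.81, and 12.69 and 11.61, against at most 11.17 and 9.75 on the other 13 arrays, both of them in heat-killed 3. Mela, a gene of retroviral origin, was at 15.88 in heat-killed 8 and 15.99 in live 8 and at most 11.19 on the others. These genes were picked after their values were seen.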
